A study of Mus musculus with 9 samples.

How the data were processed

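RNA of mouse colonic organoids was sequenced as 9 non-directional mRNA libraries, per the labels. The deposited raw counts per gene were made with Trim Galore, STAR and featureCounts in its unstranded mode on GRCm38, per the submitters' processing notes and the series design text, and the versions and annotation are not given in the sources used here. Since strand was not kept, reads of overlapping antisense genes cannot be told apart. The deposited normalized signal covers 19644 of the 54735 genes of the raw table, of which 19502 are protein coding, and 100% of its values equal the raw count times a constant for the library (tolerance 1e-06). DESeq2 is among the tools in the submitters' processing notes.

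Libraries were grouped by the guide in their titles, 3 per group. Total counts ran from 20690157 to 25733401. Gene symbols were matched to GENCODE M21 on GRCm38 for coordinates and GC content, with 98.7% matched. Replicates differed by more than sampling noise in every pair (chi-square per degree of freedom 22.3 to 205), which technical differences also give, so this does not show that they are separate samples. Each library was entered as a sample, as planned.

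The main test was edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr, glmQLFit and glmQLFTest over all 9 libraries with a mean per group and no replicate block, and Benjamini-Hochberg adjusted p under 0.05. The standard error is the size of the log2 fold change divided by the square root of the F value. In a simulation for Satb2 against control with 13592 genes tested, 33% of 2-fold and 66% of 4-fold changes were recovered and 2 of 101 calls were false. For Foxd2 against control (13614 genes) the shares were 25% and 73%, with 5 of 103 calls false. For the direct comparison (13610 genes) they were 34% and 68%, with 4 of 106 calls false. Simulated counts were drawn independently for each gene, without GC trends or other effects on a whole library. The shares of false calls therefore need not hold in the real data.

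The design, the alternatives and 27 gene lists holding 509 genes were fixed before the data were examined, and 15 genes are in more than one list. The 26 lists with at least 3 genes left by the filter were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry, which tests whether a list's genes move one way on balance. List p-values were adjusted over 78 tests, all lists and the 3 comparisons together. Named genes were Satb2, Foxd2, and for each control comparison the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a log2 CPM of at least 2, no overlap between the groups' libraries in CPM and a symbol that is not a predicted model, with 5 each way in the direct comparison, plus up to 4 members per list with the smallest adjusted p. Genes with no count in a group were bounded against 3 counts over that group, and intervals and floors cover counting error only.

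Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, a stricter filter of at least 1 CPM in 3 libraries, only the groups compared, a replicate block, each library of the groups compared left out in turn (with the filter applied anew, so that a list could hold other members), and limma on the log2 of the deposited normalized counts with pseudocounts of 1 and 0.5. A GC-content correction by a spline per library, leaving out the 2 libraries that stood apart, and leaving out the 3 libraries with the fewest genes with a count were chosen after seeing the data. Tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.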

Results

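Colonic organoids, which are epithelial cultures grown in a gel from mouse colon, had received a lentivirus with Cas9 and a guide RNA against Satb2, a guide against Foxd2 or a control guide, and had been differentiated for 4 days. Bulk RNA-seq gave 9 libraries, 3 per guide. Satb2 and Foxd2 encode DNA-binding proteins, and the comparisons asked which genes differed with each guide. Total counts per library ran from 20690157 to 25733401, and 13808 genes were tested. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Of the fibroblast and smooth muscle markers Fn1 reached 13.7 CPM (counts scaled to library size) in its highest library, Pdgfrb 4.5, Tagln 3.88 and Vim 3.61, and the others did not pass the filter for low counts. Of the immune cell markers only Laptm5 passed it, so that list was not tested, and its highest library reached 1.48 CPM.

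The targeted genes were examined first. Satb2 (chromosome 1, 56793981 to 56978650, GRCm38) had 141 ± 24.3 CPM (SD, n = 3) with the control guide, 126 ± 26.1 with the Foxd2 guide and 87.7 ± 5.92 with the Satb2 guide. Its 3 Satb2 guide libraries, at 81.9, 87.5, 93.8 CPM, all lay under the 3 control libraries, at 117, 140, 165 CPM, but the difference did not pass the threshold (log2 fold change -0.68, SE 0.18, adjusted p = 0.0794). Foxd2 (chromosome 4, 114906282 to 114908873) had 80.1 ± 17.8 CPM with the control guide and 75.9 ± 7.66 with its own guide (log2 fold change -0.08, SE 0.21, adjusted p = 0.918), so its RNA level does not check that label. With the Satb2 guide Foxd2 had 51.8 ± 10.6 CPM (log2 fold change -0.63, SE 0.21, adjusted p = 0.18). A Cas9 cut need not lower the amount of RNA, and the counts do not show whether the protein was lost.

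With the Satb2 guide, genes of small-intestinal enterocytes rose and several colonic genes fell. Sucrase-isomaltase, the brush-border disaccharidase encoded by Sis (chromosome 3, 72888557 to 72967863), rose from 24.3 ± 9.19 to 1460 ± 1156 CPM (SD, n = 3, log2 fold change 5.91, SE 0.62, adjusted p = 0.00024). Slc11a2, which carries iron into the cell, rose from 158 ± 3.45 to 1279 ± 45.4 CPM (log2 fold change 3.02, SE 0.14, adjusted p = 7.28e-07). The water channel gene Aqp8 (chromosome 7, 123462291 to 123468004) went the other way, from 79.1 ± 17 to 6.12 ± 7.12 CPM (log2 fold change -3.70, SE 0.68, adjusted p = 0.0105). In all, 418 genes passed the threshold, 285 higher and 133 lower, and 223 and 90 of these moved by a log2 value of at least 1.

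Lipid uptake and lipoprotein assembly stood out among the lists fixed beforehand. Of its 19 measured members 16 rose and 0 fell, with 17 higher and 1 lower when adjusted over the list alone, and the median log2 fold change was 2.74 (camera adjusted p = 1.08e-53, and adjusted p = 0.000689 with an estimated correlation). Mttp, which loads lipid onto apolipoprotein B, had a log2 fold change of 4.71 (SE 0.31, adjusted p = 5.9e-06), Apoa1 of 5.64 (SE 0.42, adjusted p = 1.84e-05), the retinol-binding Rbp2 of 2.79 (SE 0.22, adjusted p = 3.36e-05) and the cholesterol transporter Npc1l1 of 2.74 (SE 0.23, adjusted p = 4.57e-05). Among 15 digestive hydrolases 9 rose and 1 fell, with 14 higher and 1 lower when adjusted over the list alone (median 1.57, camera adjusted p = 7.93e-21, and adjusted p = 0.00343 with an estimated correlation). Besides Sis these included the peptidases Naaladl1, 2.36 (SE 0.19, adjusted p = 3.36e-05), Anpep, 3.76 (SE 0.35, adjusted p = 9.55e-05), and Ace2, 2.52 (SE 0.37, adjusted p = 0.0027). Among 15 nutrient transporters 12 rose and 0 fell, with 13 higher and 0 lower when adjusted over the list alone (median 1.50, camera adjusted p = 5.37e-36, and adjusted p = 0.00154 with an estimated correlation). The amino acid transporter genes Slc7a9 and Slc6a20a had values of 2.17 (SE 0.21, adjusted p = 0.000126) and 4.14 (SE 0.43, adjusted p = 0.00024), and the glucose transporter gene Slc5a1 1.29 (SE 0.15, adjusted p = 0.000455). Of 8 genes for ileal uptake of bile acids and vitamin B12, 4 rose and 0 fell, with 5 higher and 0 lower when adjusted over the list alone (median 1.28, camera adjusted p = 1.08e-07, and adjusted p = 0.0405 with an estimated correlation). They were the bile acid exporter subunit Slc51a, 1.34 (SE 0.17, adjusted p = 0.000942), the bile acid binding protein Fabp6, 5.67 (SE 0.75, adjusted p = 0.0013), Cubn, 1.67 (SE 0.25, adjusted p = 0.00316), and Amn, 1.23 (SE 0.22, adjusted p = 0.00852).

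Colonic epithelial markers moved down as a list. Of 20 measured members 7 fell and 1 rose, with 1 higher and 11 lower when adjusted over the list alone (median -0.75, camera adjusted p = 3.72e-13, and adjusted p = 0.00271 with an estimated correlation). The carbonic anhydrase gene Car1 went from 14307 ± 1256 to 4879 ± 786 CPM (log2 fold change -1.55, SE 0.15, adjusted p = 0.000118), Ly6g had a log2 fold change of -1.22 (SE 0.14, adjusted p = 0.000538) and the proton pump gene Atp12a -2.96 (SE 0.42, adjusted p = 0.00212), while Ceacam20 rose (log2 fold change 0.94, SE 0.14, adjusted p = 0.00247). The ion and water transport list went both ways, 2 of 25 members higher and 8 lower (9 higher and 9 lower when adjusted over the list alone), and its median of 0.05 and mean of 0.08 were positive while camera's direction was down (camera adjusted p = 0.361, and adjusted p = 0.448 with an estimated correlation). With 1 library left out the median ran from 0.06 to 0.21. The anion exchanger gene Slc26a6 and the sodium channel subunit Scnn1a rose, by log2 values of 5.16 (SE 0.26, adjusted p = 1.11e-06) and 2.14 (SE 0.18, adjusted p = 4.57e-05), and Car2 had -1.39 (SE 0.13, adjusted p = 9.35e-05).

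Among genes with a log2 CPM of at least 2 that met the rule for named genes, the largest rises also held detoxifying enzymes. Cyp2c29 (chromosome 19, 39269405 to 39330713) had no count in the control libraries and 54 ± 38 CPM with the Satb2 guide, at least 1240-fold higher against a floor of 3 counts over the control group (edgeR adjusted p = 0.000203). Adh4, an alcohol dehydrogenase, had 2 control counts in all and a ratio of 979 (95% counting interval 271 to 8092, adjusted p = 4.9e-06). Besides Sis, given above, the others were Cyp2c66, 7.77 (SE 0.82, adjusted p = 0.00024), Myrf, 7.59 (SE 0.69, adjusted p = 8.85e-05), the annexin Anxa13, 6.71 (SE 0.28, adjusted p = 4.88e-07), the lysozyme Lyz1, 6.64 (SE 0.76, adjusted p = 0.000418), the peptidase Mme, 6.26 (SE 1.12, adjusted p = 0.00881), Adh6a, 5.90 (SE 0.50, adjusted p = 4.57e-05), and the galectin Lgals2, 5.88 (SE 0.35, adjusted p = 3.78e-06). Members of the Cyp2c, Ces2, Adh, Defa, Ly6, Ceacam and lysozyme families resemble each other, so reads could be divided among them. The xenobiotic metabolism list had 10 of 25 members higher and 1 lower, with 12 higher and 3 lower when adjusted over the list alone (median 0.69, camera adjusted p = 1.11e-14, and adjusted p = 0.0531 with an estimated correlation). Abcc2, 3.65 (SE 0.21, adjusted p = 2.93e-06), and Ces2a, 2.86 (SE 0.19, adjusted p = 8.55e-06), were among those that rose. In single libraries the median against the control mean was 1.23 in Satb2 guide replicate 2, which stood apart, but 0.48 and 0.0091 in replicates 1 and 3, and without replicate 2 the list's median was 0.29, still called by camera.

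Among genes with a log2 CPM of at least 2 by the same rule, the largest falls were led by the calcium channel gene Ryr2 (chromosome 13, 11553102 to 12106945), which went from 36.8 ± 9.12 to 2.29 ± 1.08 CPM (log2 fold change -4.01, SE 0.38, adjusted p = 0.000124). Aqp8 followed, then the metalloreductase gene Steap4, -3.27 (SE 0.48, adjusted p = 0.0027), the peroxidase gene Lpo, -2.99 (SE 0.37, adjusted p = 0.0007), the phosphatase gene Ptpn5, -2.99 (SE 0.40, adjusted p = 0.0013), Atp12a, Padi2, -2.87 (SE 0.46, adjusted p = 0.00392), and the lipid transporter gene Abca12, -2.80 (SE 0.24, adjusted p = 4.57e-05). The sodium-hydrogen exchanger gene Slc9a3 went from 488 ± 87.3 to 70.7 ± 42.2 CPM (log2 fold change -2.79, SE 0.37, adjusted p = 0.00133) and the adrenergic receptor gene Adra2a had -2.65 (SE 0.41, adjusted p = 0.0036). The ketogenic enzyme gene Hmgcs2 also fell (log2 fold change -2.29, SE 0.27, adjusted p = 0.000538).

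Of the Paneth, goblet, enteroendocrine, transcription factor and cholesterol biosynthesis lists, only the last was called at an estimated correlation with the Satb2 guide. Of 18 listed Paneth cell markers only 6 passed the filter for low counts, and 1 of these had no count in a whole group. A gene near silent in the controls can pass that filter through a group where it is high, which can raise the median. Of the 6 measured members 3 were higher and 0 lower, and 5 higher and 0 lower when adjusted over the list alone. Its median was 3.10 (camera adjusted p = 4.68e-07, adjusted p = 0.126 with an estimated correlation). Lyz1, the protease gene Mmp7, 1.89 (SE 0.37, adjusted p = 0.0152), and the lectin gene Itln1, 4.32 (SE 0.90, adjusted p = 0.0216), passed the threshold. Goblet cell markers had 2 of 21 members higher and 0 lower, and 4 higher and 0 lower when adjusted over the list alone. Over the members the median was 0.33 (0.21 to 0.43 with 1 library left out, camera adjusted p = 0.00126, adjusted p = 0.22 with an estimated correlation). The mucus-associated gene Fcgbp rose (log2 fold change 1.75, SE 0.19, adjusted p = 0.00031), as did Spink4 (log2 fold change 1.49, SE 0.35, adjusted p = 0.0388). Enteroendocrine markers had 1 of 18 members higher and 1 lower, and 4 higher and 1 lower when adjusted over the list alone. Here the median was 0.58 (0.33 to 0.90 with 1 library left out, camera adjusted p = 0.0818, adjusted p = 0.474 with an estimated correlation). The list was called without Satb2 guide replicate 1 or Satb2 guide replicate 3, or with no low-count filter, with only the groups compared or with the replicate block. The hormone genes Insl5 and Cck had -2.51 (SE 0.45, adjusted p = 0.00881) and 1.29 (SE 0.30, adjusted p = 0.0391). Transcription factors had 6 of 27 members higher and 0 lower, and 9 higher and 2 lower when adjusted over the list alone. Their median was 0.14 (0.09 to 0.38 with 1 library left out, camera adjusted p = 0.00441, adjusted p = 0.22 with an estimated correlation). Those that rose included Maf, 1.36 (SE 0.15, adjusted p = 0.00031), Creb3l3, 1.45 (SE 0.20, adjusted p = 0.00173), and Hnf4g, 1.72 (SE 0.32, adjusted p = 0.0114). Cholesterol biosynthesis had 1 of 22 members higher and 0 lower, and 4 higher and 0 lower when adjusted over the list alone. Across them the median was 0.42 (camera adjusted p = 1.17e-05, adjusted p = 0.0179 with an estimated correlation). Its member past the threshold was Pcsk9 (log2 fold change 0.73, SE 0.17, adjusted p = 0.0411).

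None of the further lists was called at an estimated correlation with the Satb2 guide. The stem cell and Wnt target list, with a positive median and mean while camera pointed down, had 1 of 14 members higher and 0 lower, and 1 higher and 1 lower when adjusted over the list alone. For this list the median was 0.05 (-0.08 to 0.12 with 1 library left out, camera adjusted p = 0.991, adjusted p = 0.995 with an estimated correlation). For fatty acid oxidation and PPAR targets the values were 3 of 20 members higher and 1 lower, and 4 higher and 1 lower when adjusted over the list alone. Its median was 0.18 (0.12 to 0.26 with 1 library left out, camera adjusted p = 0.298, adjusted p = 0.53 with an estimated correlation). Antimicrobial lectins and defence gave 2 of 11 members higher and 1 lower, and 5 higher and 2 lower when adjusted over the list alone. Over the members the median was 0.19 (0.09 to 0.81 with 1 library left out, camera adjusted p = 0.071, adjusted p = 0.22 with an estimated correlation). It was called without Satb2 guide replicate 1, or with no low-count filter, with only the groups compared, without the 3 libraries with the fewest genes or with fry. The posterior Hox list, which also holds lower-numbered genes such as Hoxa7 and Hoxb8, had 0 of 11 members higher and 1 lower. It had 1 higher and 1 lower when adjusted over the list alone. Here the median was -0.17 (-0.28 to -0.02 with 1 library left out, camera adjusted p = 0.245, adjusted p = 0.464 with an estimated correlation). In the proliferation list there were 0 of 25 members higher and 0 lower, and no member when adjusted over the list alone. Their median was 0.60 (0.18 to 0.80 with 1 library left out, camera adjusted p = 0.0045, adjusted p = 0.562 with an estimated correlation). The call was lost without Satb2 guide replicate 2, or without the 2 libraries that stood apart or with fry. Interferon response genes showed 0 of 21 members higher and 0 lower, and no member when adjusted over the list alone. Across them the median was -0.24 (-0.69 to -0.12 with 1 library left out, camera adjusted p = 0.0165, adjusted p = 0.403 with an estimated correlation). It was no longer called without control replicate 1, control replicate 3 or Satb2 guide replicate 2, or with GC correction, without the 2 libraries that stood apart, without the 3 libraries with the fewest genes or with fry. For the unfolded protein and integrated stress response there were 0 of 17 members higher and 0 lower, and 3 higher and 0 lower when adjusted over the list alone. For this list the median was 0.25 (0.14 to 0.39 with 1 library left out, camera adjusted p = 0.0259, adjusted p = 0.233 with an estimated correlation). That call ended without control replicate 1, control replicate 3 or Satb2 guide replicate 3, or without the 2 libraries that stood apart. Mitochondrially encoded transcripts had 0 of 12 members higher and 0 lower, and no member when adjusted over the list alone. Its median was 1.18 (0.07 to 1.85 with 1 library left out, camera adjusted p = 0.083, adjusted p = 0.707 with an estimated correlation). The list was called without control replicate 3, Satb2 guide replicate 1 or Satb2 guide replicate 3, or with DESeq2, with no low-count filter or without the 3 libraries with the fewest genes. Mitochondrial genes took 1.64% of the counts in Satb2 guide replicate 2 and 0.104 to 0.541% in the other libraries. The proliferation median of log2 CPM less the control mean was 1.20 in that replicate and 0.24 and 0.14 in the others. Tuft cell markers had 0 of 6 members higher and 0 lower, and no member when adjusted over the list alone. Over the members the median was 0.32 (0.39 to 2.75 with 1 library left out, camera adjusted p = 0.589, adjusted p = 0.71 with an estimated correlation). The fetal-like list gave 0 of 16 members higher and 0 lower, and no member when adjusted over the list alone. Here the median was 0.20 (0.14 to 0.33 with 1 library left out, camera adjusted p = 0.215, adjusted p = 0.616 with an estimated correlation). It was called without Satb2 guide replicate 1. MHC class II genes had 0 of 5 members higher and 0 lower, and no member when adjusted over the list alone. Their median was -0.14 (-0.42 to -0.04 with 1 library left out, camera adjusted p = 0.263, adjusted p = 0.403 with an estimated correlation). For p53 target genes there were 0 of 20 members higher and 0 lower, and no member when adjusted over the list alone. Across them the median was 0.09 (-0.06 to 0.19 with 1 library left out, camera adjusted p = 0.549, adjusted p = 0.806 with an estimated correlation). Immediate early and heat shock genes had 0 of 17 members higher and 1 lower, and 1 higher and 1 lower when adjusted over the list alone. For this list the median was 0.20 (-0.00 to 0.32 with 1 library left out, camera adjusted p = 0.799, adjusted p = 0.973 with an estimated correlation). Fibroblast and smooth muscle markers had 0 of 4 members higher and 0 lower, and no member when adjusted over the list alone. Its median was -0.27 (-0.66 to -0.02 with 1 library left out, camera adjusted p = 0.341, adjusted p = 0.501 with an estimated correlation).

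The number of changed genes with the Satb2 guide depended on the libraries. It was 244 without control replicate 2, 250 without Satb2 guide replicate 1 and 723 without Satb2 guide replicate 2, and 19 of the 20 named genes with the largest changes (log2 CPM of at least 2) stayed past the threshold whichever of the 6 Satb2 guide and control libraries was left out, the exception being Aqp8. Control replicate 3 and Satb2 guide replicate 2 stood apart from their replicates. Their chi-square per degree of freedom ran from 53 to 85.6 and from 128 to 205, against 23.7 and 35.6 between the other replicates. Leaving them out lowers the spread within groups, which can by itself raise the count. Without these libraries 16 of the lipid genes rose, 1 fell and 889 genes changed in all. Without the 3 libraries with the fewest genes with a count (control replicate 3, Foxd2 guide replicate 2 and Satb2 guide replicate 1) 12 rose, 0 fell and 100 changed in all.

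**Figure D1:**
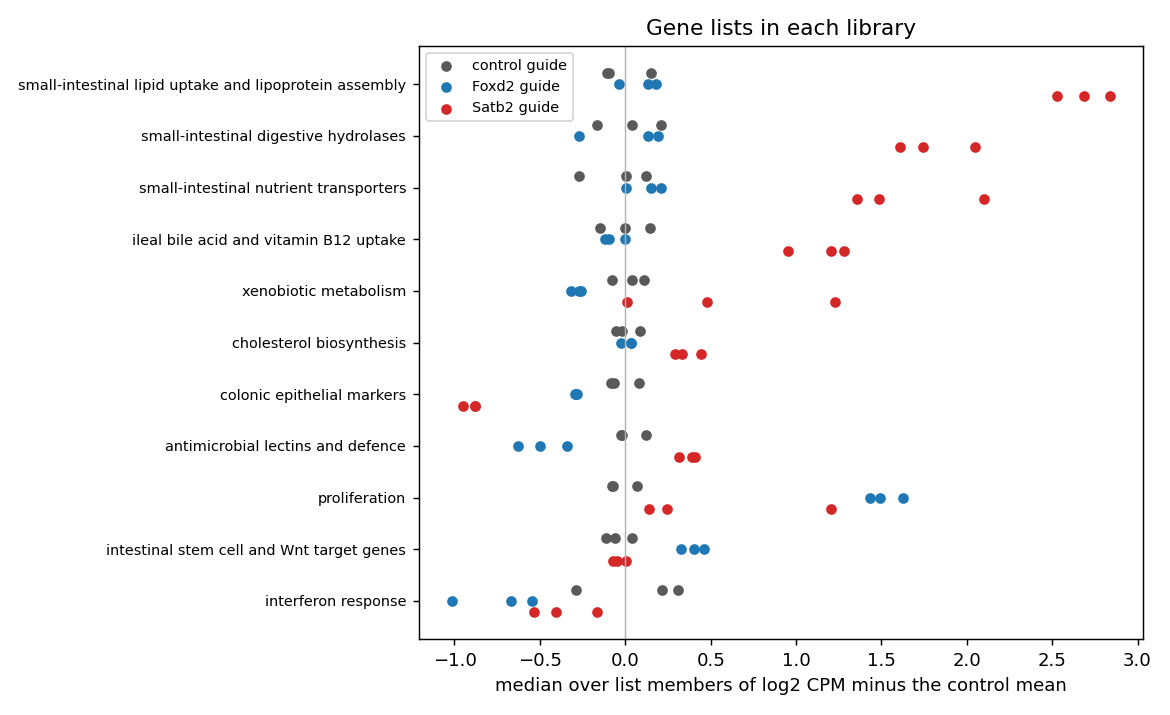
Median over the members of each gene list of log2 CPM less the control mean, with a point for each library in the 3 guide groups. The lipid uptake medians of the Satb2 guide libraries lie between 2.53 and 2.84, and the proliferation medians of the Foxd2 guide libraries between 1.43 and 1.63.

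With the Foxd2 guide few genes passed the threshold. Of 18 genes 16 were higher and 2 lower. Uhrf1 (chromosome 17, 56303321 to 56323486), which maintains DNA methylation, rose from 3.11 ± 0.702 to 15 ± 0.98 CPM (SD, n = 3, log2 fold change 2.27, SE 0.29, adjusted p = 0.0259). The replicative helicase subunit Mcm2 rose (log2 fold change 2.09, SE 0.31, adjusted p = 0.0329), as did the mitotic regulators Cdc20, 2.08 (SE 0.25, adjusted p = 0.0259), Racgap1, 1.96 (SE 0.31, adjusted p = 0.0434), Ube2c, 1.58 (SE 0.22, adjusted p = 0.0259), and Cdca3, 1.46 (SE 0.23, adjusted p = 0.0434).

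Srm and Cad, enzymes of polyamine and pyrimidine synthesis, had log2 fold changes of 1.83 (SE 0.28, adjusted p = 0.0402) and 1.50 (SE 0.19, adjusted p = 0.0259). The keratin gene Krt4 went from 254 ± 47.9 to 639 ± 100 CPM (log2 fold change 1.33, SE 0.19, adjusted p = 0.0323) and the peroxidase gene Gpx2 had 1.21 (SE 0.18, adjusted p = 0.0329). The genes that fell were the caveolin gene Cav1 (chromosome 6, 17306335 to 17341452, log2 fold change -1.34, SE 0.22, adjusted p = 0.0434) and the interferon-inducible Ifit1bl1 (log2 fold change -1.29, SE 0.18, adjusted p = 0.0259).

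The proliferation list had 2 of 25 members higher, Ube2c and Mcm2, and 0 lower, but 21 higher and 0 lower when adjusted over the list alone. Its median log2 fold change was 1.57 (camera adjusted p = 2.15e-32, and adjusted p = 0.0585 with an estimated correlation). Mcm5 and Plk1 had values of 2.65 (SE 0.45, adjusted p = 0.0558) and 1.92 (SE 0.35, adjusted p = 0.0709). Interferon response genes had 0 of 21 members higher and 0 lower, and 0 higher and 8 lower when adjusted over the list alone. Over the members the median was -0.84 (camera adjusted p = 2.28e-10, adjusted p = 0.0617 with an estimated correlation). Ifit1 had -1.84 (SE 0.33, adjusted p = 0.067). Antimicrobial lectins and defence had 0 of 11 members higher and 0 lower, and 0 higher and 4 lower when adjusted over the list alone. Here the median was -0.49 (camera adjusted p = 7.83e-05, adjusted p = 0.028 with an estimated correlation). Colonic markers had 0 of 20 members higher and 0 lower, and 0 higher and 4 lower when adjusted over the list alone. Their median was -0.40 (-0.32 to -0.13 with 1 library left out, camera adjusted p = 0.000648, adjusted p = 0.0361 with an estimated correlation). The stem cell and Wnt target list had 0 of 14 members higher and 0 lower, and 5 higher and 1 lower when adjusted over the list alone. Across them the median was 0.36 (0.24 to 0.42 with 1 library left out, camera adjusted p = 0.000665, adjusted p = 0.0617 with an estimated correlation). Cdca7 had 1.03 (SE 0.23, adjusted p = 0.124) and Myc 0.73 (SE 0.20, adjusted p = 0.186), neither past the threshold.

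Other lists called by camera in this comparison lost the call with an estimated correlation. Paneth markers, with 6 of 18 listed genes measured, gave 0 members higher and 0 lower, and 2 higher and 0 lower when adjusted over the list alone. For this list the median was 1.32 (0.81 to 1.64 with 1 library left out, camera adjusted p = 0.00242, adjusted p = 0.299 with an estimated correlation). The call was lost with only the groups compared or with fry. Xenobiotic metabolism gave 0 of 25 members higher and 0 lower, and no member when adjusted over the list alone. Its median was -0.33 (camera adjusted p = 0.00467, adjusted p = 0.363 with an estimated correlation). It was no longer called with fry. Fatty acid oxidation gave 0 of 20 members higher and 0 lower, and 0 higher and 1 lower when adjusted over the list alone. Over the members the median was -0.17 (camera adjusted p = 0.0177, adjusted p = 0.22 with an estimated correlation). That call ended without control replicate 1, or without the 3 libraries with the fewest genes. The posterior Hox list gave 0 of 11 members higher and 0 lower, and 1 higher and 0 lower when adjusted over the list alone. Here the median was 0.31 (0.13 to 0.43 with 1 library left out, camera adjusted p = 0.0413, adjusted p = 0.242 with an estimated correlation). The call was lost without control replicate 1, control replicate 2 or Foxd2 guide replicate 3, or with the stricter filter, with the replicate block, with limma at both pseudocounts or with GC correction. The 3 small-intestinal lists were not called in the main test. Lipid uptake had 0 of 19 members higher and 0 lower, and 1 higher and 0 lower when adjusted over the list alone. Their median was 0.11 (-0.03 to 0.14 with 1 library left out, camera adjusted p = 0.0506, adjusted p = 0.259 with an estimated correlation). The list was called without control replicate 1, Foxd2 guide replicate 1 or Foxd2 guide replicate 2, or with DESeq2, with DESeq2's size factors in edgeR, with no low-count filter or without the 3 libraries with the fewest genes. Digestive hydrolases had 0 of 15 members higher and 0 lower, and 0 higher and 1 lower when adjusted over the list alone. Across them the median was 0.11 (-0.12 to 0.13 with 1 library left out, camera adjusted p = 0.991, adjusted p = 0.995 with an estimated correlation). Nutrient transporters had 0 of 15 members higher and 0 lower, and 1 higher and 3 lower when adjusted over the list alone. For this list the median was 0.12 (-0.01 to 0.35 with 1 library left out, camera adjusted p = 0.95, adjusted p = 0.974 with an estimated correlation). Camera's direction for transporters was down.

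The count for the Foxd2 guide depended on the libraries. It was 3 without control replicate 1 and 0 in edgeR without control replicate 2 or 3 or any Foxd2 guide replicate. In the fits with 0, from 873 genes (of 14329 tested, without Foxd2 guide replicate 3) to 1292 (of 14352, without control replicate 2) had an unadjusted p under 0.05. With no change at all, a share of about 0.05 of the tested genes would have such a p. With all libraries 1552 genes had such a p, DESeq2 called 330 and a fit of only the groups compared gave 127. Leaving out control replicate 3 and Satb2 guide replicate 2 gave 280 genes, 20 of them in the proliferation list, and leaving out the 3 libraries with the fewest genes gave 0, with 845 at an unadjusted p under 0.05.

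The direct comparison of both guides, which tests whether their effects differ, gave 523 genes, 366 higher and 157 lower with the Satb2 guide. Among genes with a log2 CPM of at least 2 that met the rule for named genes, the largest rises were Cyp2c29, 9.83 (SE 0.87, adjusted p = 0.000269), Adh4 with 3 counts in all with the Foxd2 guide and a ratio of 706 (95% counting interval 241 to 3425), Adh6a, 7.36 (SE 0.55, adjusted p = 1.94e-05), Anxa13, 7.20 (SE 0.29, adjusted p = 1.94e-07), and Cyp2c66, 7.18 (SE 0.78, adjusted p = 0.000324). By the same rule the largest falls were Atp12a, -3.92 (SE 0.43, adjusted p = 0.000341), Aqp8, -3.39 (SE 0.68, adjusted p = 0.017), Padi2, -2.47 (SE 0.45, adjusted p = 0.0107), Lpo, -2.42 (SE 0.36, adjusted p = 0.0029), and Ryr2, -2.37 (SE 0.36, adjusted p = 0.00338). Of these 10 genes 8 passed whichever of the 6 libraries of both guides was left out. Aqp8 did not pass without Foxd2 guide replicate 2 or 3 or Satb2 guide replicate 1 (largest adjusted p 0.0844), nor Padi2 without Satb2 guide replicate 1 (adjusted p = 0.0572). Lipid uptake genes had 13 of 19 members higher and 0 lower, and 17 higher and 0 lower when adjusted over the list alone. Its median was 2.36 (camera adjusted p = 1.62e-40, adjusted p = 0.00118 with an estimated correlation). Antimicrobial genes had 5 of 11 members higher and 1 lower, and 7 higher and 1 lower when adjusted over the list alone. Over the members the median was 1.30 (camera adjusted p = 3.28e-06, adjusted p = 0.0179 with an estimated correlation). Nos2 had 2.71 (SE 0.26, adjusted p = 0.000148) and Reg3b 3.26 (SE 0.42, adjusted p = 0.000917). Proliferation genes had 0 of 25 members higher and 2 lower, and 0 higher and 15 lower when adjusted over the list alone. Here the median was -0.89 (-1.40 to -0.73 with 1 library left out, camera adjusted p = 8.3e-10, adjusted p = 0.235 with an estimated correlation). Without 1 library the count ran from 189 (Foxd2 guide replicate 3) to 974 (Satb2 guide replicate 2), being 200 and 228 without Foxd2 guide replicates 1 and 2 and 235 and 848 without Satb2 guide replicates 1 and 3. The 189 were 157 higher and 32 lower, and the 974 were 570 higher and 404 lower.

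Krt4 and Baiap2l2 rose and Cav1 fell with both guides, 3 genes in all, and 0 moved in opposite directions. With the Satb2 guide Krt4 had 508 ± 88.3 CPM (adjusted p = 0.0128), Cav1 a log2 fold change of -0.91 (SE 0.21, adjusted p = 0.0423) and Baiap2l2 1.47 (SE 0.19, adjusted p = 0.000942), against 1.15 (SE 0.19, adjusted p = 0.0439) for Baiap2l2 with the Foxd2 guide. Baiap2l2 was named after its values were seen. The overlap was 2 without control replicate 1 and 0 in edgeR without control replicate 2 or 3, with the replicate block or without the 3 libraries with the fewest genes, and 68 with DESeq2. Unchanged groups simulated against shared controls gave an overlap of 0 in 20 datasets, which is no yardstick since unchanged groups give few calls. Independent lists would share 0.33 higher and 0.0193 lower genes. Across genes, which are not independent replicates, the fold changes had a correlation of 0.38, against 0.50 in the simulations, and a covariance of 0.192 against 0.121. With 3 control libraries the controls could not be split into parts of at least 2, so part of the overlap and of the covariance may come from the shared controls.

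**Figure D2:**
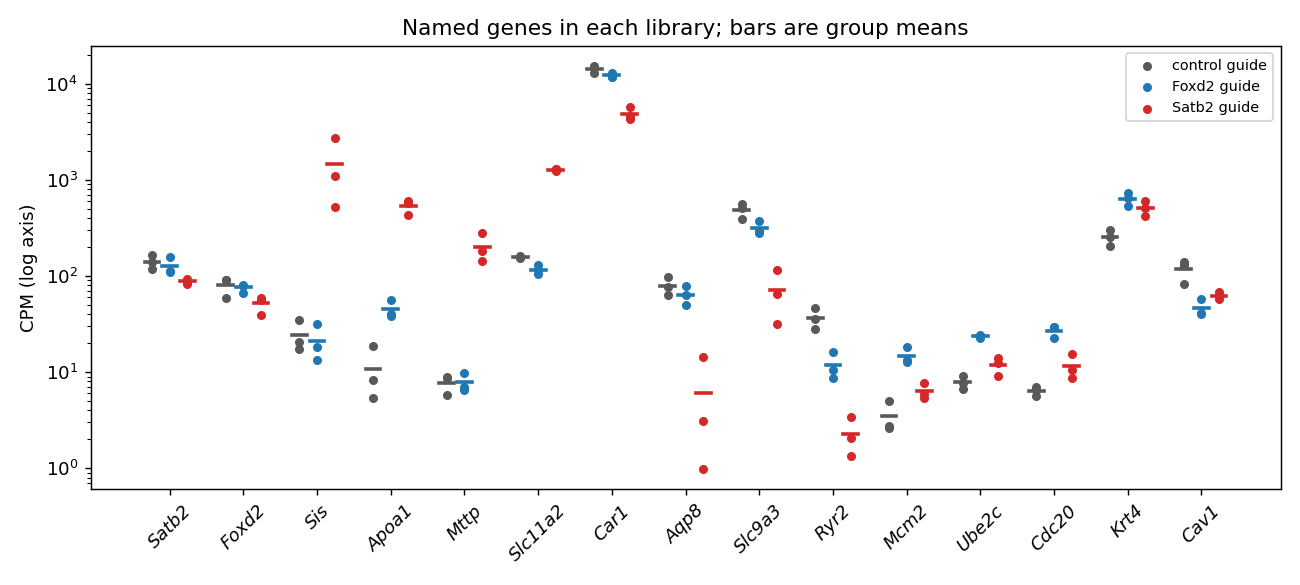
CPM on a log axis of named genes in each of the 9 libraries, with bars at the group means. Sis had a mean of 24.3 CPM with the control guide and 1460 with the Satb2 guide, and Mcm2 3.46 with the control guide and 14.8 with the Foxd2 guide.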

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

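The tests of GC content, of mixed-in cells, and of single libraries below were chosen after the results they bear on had been seen. In the direct comparison 8 lists differed between the effects of both guides in camera, with an estimated correlation and in fry. Their median log2 differences were 2.36 for lipid uptake and lipoprotein assembly, 1.67 for nutrient transporters, 1.39 for digestive hydrolases, 1.30 for antimicrobial lectins and defence, 1.13 for xenobiotic metabolism, 0.85 for ileal bile acid and vitamin B12 uptake, 0.41 for cholesterol biosynthesis and -0.67 for colonic epithelial markers. The xenobiotic value was 0.48 without Satb2 guide replicate 2 and 0.49 without that library and control replicate 3. For colonic markers it ran from -0.63 to -0.35 with 1 library left out.

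Small-intestinal genes were higher and colonic markers lower with the Satb2 guide. A GC trend took 36.6% of the variance in Satb2 guide replicate 2, but with it removed the median over the 3 small-intestinal lists was 2.19 against 2.29 before, with every list still called at an estimated correlation, which argues against that trend as the whole source. Dilution by small-intestinal cells would lower Hox genes that such cells lack by as much as the colonic markers that fell, whose median was -1.55. Those were the 7 of 20 markers that fell past the threshold in this same comparison. This picks the larger falls, and the median of the whole list was -0.75. The mean of Hoxa10 and Hoxa13 was -0.00105 (SE 0.19). The mean less 2 standard errors was -0.39, a smaller fall than either median of the colonic markers. For these 2 genes that argues against such cells as the whole source of the colonic fall. It does not exclude such cells, since only 2 genes, assumed absent from small-intestinal cells, carry this. They were chosen after a first test over 4 Hox genes with a like outcome had been seen. At that bound of the mean less 2 standard errors, the same genes leave room for up to 23.5% of mixed-in cells. The bound takes the 2 genes as independent, though both were measured in the same libraries. Such cells as a source of the small-intestinal rise therefore cannot be told apart from an effect of the guide, which may also be a cause.

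With the Foxd2 guide camera called the proliferation list higher at the preset correlation, while 2 of 25 members passed over all genes and the call was lost with an estimated correlation (adjusted p = 0.0585). With the GC trend removed the median was 1.43 against 1.57, and with any of the 6 control and Foxd2 guide libraries left out it was at least 1.46 and stayed called by camera, which argues against both as the whole source. After GC correction the estimated correlation gave an adjusted p of 0.0518. The list's median of log2 CPM less the control mean was 1.43 in the lowest Foxd2 guide library and 0.07 in the highest control library. A difference in growth stage between the groups at harvest could also give this and was not tested. Other lists, such as the colonic markers and the stem cell and Wnt targets, also moved with this guide. The guide itself could move them too, so gene levels cannot separate stage from guide, and no other measure of stage was at hand.

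Other ways to split the 6 libraries of a comparison into 3 and 3 number 10 with the real one, so the smallest share they can give is 0.1, and they are too few for one under 0.05. The real split gave 418 genes for Satb2 against control, 18 for Foxd2 against control and 523 for the direct comparison, and the highest count of any other split was 0, 0, 0 in that order. As many genes were found in 1, 1, 1 of the splits, the real one included. Every other split mixes libraries of both guides within a group, so a real difference would add to its spread. The counts of 0 there are therefore no separate support.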

How the results depend on the processing

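The GC correction and both settings that left out doubted libraries were chosen after the data were seen. The main counts were 418 genes for Satb2 against control, 18 for Foxd2 against control, 523 for the direct comparison and 3 in both control comparisons with the same sign. In that order they were 814, 330, 1104 and 68 with DESeq2, 792, 267, 1147 and 57 with no low-count filter, 853, 174, 1201 and 46 with GC correction, 889, 280, 2138 and 57 without control replicate 3 and Satb2 guide replicate 2, and 100, 0, 84 and 0 without the 3 libraries with the fewest genes. With only the groups compared they were 233, 127, 483 and 12, and with a replicate block 318, 0, 328 and 0. The stricter filter gave 1 gene in both. Leaving out in turn each of the 6 libraries of the groups compared gave 244 to 723, 0 to 3 and 189 to 974, and leaving out each of the 3 control libraries gave 0 to 2 in both. The counts 0 are edgeR's, beside 1291 genes (of 13808 tested) with an unadjusted p under 0.05 for Foxd2 under the block and 845 (of 13899) without the 3 libraries. With no change at all, a share of about 0.05 of the tested genes would have such a p. The causes were not tested. Fewer libraries leave less power, yet the counts rose without control replicate 3 and Satb2 guide replicate 2. For Foxd2 against control the count was 0 without control replicate 3 alone and 280 without Satb2 guide replicate 2 as well. That Satb2 guide library is not in this comparison but shares its estimate of the spread. GC correction gave 477 higher and 376 lower genes for Satb2 and 93 and 81 for Foxd2. Of 9 same-numbered pairs of libraries, 1 had a correlation of deviations over 0.1, while pairs of other numbers ran from -0.28 to 0.32. These correlations give no sign that the numbers pair the libraries, but with 3 libraries per group they cannot exclude it. The proliferation median of 1.57 with the Foxd2 guide was no longer called with an estimated correlation (adjusted p = 0.0585). No gene or list called in the main test was called in the other direction by an alternative, but the proliferation median for Satb2 against control, called at 0.60, was -0.00429 and no longer called without control replicate 3 and Satb2 guide replicate 2. Of 5865 values of named genes 311 lost a call, 284 gained one and 41 uncalled ones changed sign. Of 1479 list tests 72 lost a call, 39 gained one and 72 uncalled ones changed the direction given by the test, which need not be the sign of the median. Simulated 2-fold changes were mostly missed at this depth and number of libraries.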

Other observations

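In the direct comparison the posterior Hox list had 0 of 11 members higher and 2 lower. When adjusted over the list alone 0 were higher and 3 lower. Their median was -0.56 (camera adjusted p = 0.00532, adjusted p = 0.123 with an estimated correlation). Hoxb8 had a log2 fold change of -1.05 (SE 0.17, adjusted p = 0.00466) and Hoxa7 of -1.68 (SE 0.34, adjusted p = 0.0183). Both are lower-numbered genes of the list. Hoxa10 and Hoxa13 had -0.05 (SE 0.29) and 0.05 (SE 0.26) for Satb2 against control. Fatty acid oxidation and PPAR targets had 2 of 20 members higher and 1 lower, and 7 higher and 1 lower when adjusted over the list alone. Across them the median was 0.44 (0.22 to 0.43 with 1 library left out, camera adjusted p = 0.0045, adjusted p = 0.155 with an estimated correlation). Vnn1 had 1.50 (SE 0.26, adjusted p = 0.00827) and Hmgcs2 -1.22 (SE 0.26, adjusted p = 0.0248). The unfolded protein and integrated stress response list had 2 of 17 members higher and 1 lower, and 7 higher and 2 lower when adjusted over the list alone. For this list the median was 0.33 (0.20 to 0.44 with 1 library left out, camera adjusted p = 0.0321, adjusted p = 0.254 with an estimated correlation). It was no longer called without Foxd2 guide replicate 3 or Satb2 guide replicate 3, or with only the groups compared or without the 2 libraries that stood apart. In it Chac1 had 1.29 (SE 0.27, adjusted p = 0.0214) and Phgdh -0.81 (SE 0.19, adjusted p = 0.0323).

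Foxd2os, a transcript named after the opposite strand of Foxd2 and picked after its values were seen, had 13.9 ± 1.31 CPM with the control guide, 7.94 ± 0.59 with the Foxd2 guide (log2 fold change -0.80, SE 0.27, adjusted p = 0.297) and 9.1 ± 3.49 with the Satb2 guide (log2 fold change -0.61, SE 0.27, adjusted p = 0.367). The libraries kept no strand.

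Libraries differed in the number of genes with a count. Control replicate 3 had 14166, Satb2 guide replicate 1 15294 and Foxd2 guide replicate 2 15605, while the others had 17284 to 19289. Genes with at least 10 counts numbered 12969 to 13648 in all of them.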
